A study of Mus musculus with 24 samples.

How the data were processed

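Liver RNA of adult male Ghr-floxed mice on the C57BL/6 strain was sequenced, per the labels, after polyA selection, 7 days after a tail vein injection of adeno-associated virus serotype 8 (AAV8). Every sample is labelled male and the series' design names male livers, whereas the treatment protocol speaks of littermates of both sexes. The group values, looked at after the data were seen, are low for Xist in all groups, but the table holds no female liver to set a bound on single animals. The 24 libraries fall into 4 groups of 6 animals, taken from the labels. All vectors carry the thyroxine-binding globulin promoter, which is active in hepatocytes. Control animals received an empty (Null) vector. The group aHepGHRkd received a Cre recombinase vector at a dose of 1.5 (in units of 1e+11 genome copies). Cre removes the floxed part of the growth hormone receptor gene Ghr from hepatocytes. The group aHepGHRkd_rIGF1 received Cre and a rat IGF1 vector at a dose of 2.0 in that unit, and aHepGHRkd_STAT5bCA received Cre and a constitutively active mouse STAT5b at 0.75. The total was 3.5 in every animal, with Null vector making up what the other vectors left. By these doses the aHepGHRkd_rIGF1 group needed no Null vector, so its dose differs between groups. Control animals differ from the others in Cre as well as in Ghr.

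One table was used. Per the file headers, it lists 75798 features of exon-collapsed gene models on the mouse build mm9, and 75794 of them were read, since 4 lines were left empty in the copy used here. The authors used STAR, featureCounts and edgeR, per the submitters' processing notes, with versions not given in the sources used here. Whether the counting used strand is not given in the sources used here. The table is a summary by the authors and carries no value for any single animal. TPM (length-normalised transcript abundance) in the authors' deposited table is 1 value per group, and the values of a group add up to between 999981 and 999989. Ratio, the fold between 2 groups on a linear scale, was computed by the authors with edgeR, per the file headers. It follows the ratio of the group TPM values with 1 scaling difference per comparison, whose median on the log2 scale was 0.02 for aHepGHRkd over Control, 0.10 for aHepGHRkd_rIGF1 over aHepGHRkd and fell by 0.05 for aHepGHRkd_STAT5bCA over aHepGHRkd. No called feature changed direction when the TPM ratio was used in place of the deposited ratio.

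The p-value column of the authors' deposited table is headed P-1 and its header does not state an adjustment. It was read as a Benjamini-Hochberg adjusted p, because 69174, 75054 and 72384 of its values are exactly 1 in the 3 comparisons in the order above. The 740 values under 1 of the rIGF1 comparison also hold only 202 distinct numbers. A fold of at least 2 with a value under 0.05 gives 216 features up and 526 down for the knockdown, the counts in the header. For aHepGHRkd_STAT5bCA the header gives 575 up and 574 were counted. The smallest value printed, 9e-301, is shared by several features and was taken as a floor.

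The tests planned before the data were examined need a value per library, so edgeR, which the authors used, was not run here. Nor could limma across the 24 libraries, camera and fry for gene lists, a replicate block, left-out replicates or a split of the aHepGHRkd libraries be run on group values. No standard deviation, n or test between animals is therefore given beyond the authors' own p. Depth per library is unknown, since TPM keeps no depth, and a value of exactly 0 is described as listed at 0, with no fold against it. A feature was called higher or lower when its deposited p was under 0.05. Coding features (20879) are those whose gene type is an NM accession, the other 54915 are noncoding, and counts are given for both. Symbols stand in capitals in the table, and 20699 of the coding symbols matched a mouse RefSeq symbol regardless of case, which was then printed. Coordinates are those of the table, on mm9.

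For each of 29 gene lists fixed before the data were examined, the members called higher and lower were counted. The count adjusted over the list alone used the largest unadjusted p that the deposited value allows (value times its last rank over the number of features detected in either group), so it is a lower limit and is given as "at least". This rests on the reading of the p column given above. Over-representation of a list among called genes was tested by a one-sided Fisher's exact test against the 14081 coding genes that reached 0.1 TPM in any group, with Benjamini-Hochberg adjustment over the lists and both directions within a comparison. Genes are not independent of each other, so these p-values are smaller than a test across animals would give. The background was raised to 1 TPM as an alternative chosen after the data were seen. A list's median log2 ratio was set against 10000 random lists matched on mean TPM in 10 bins, as a description. Group values were compared on the log2(TPM + 1) scale, or with a pseudocount of 0.1, where the table has no test. On such a scale the change of low genes is understated.

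Named genes follow a rule fixed before the data were examined. It takes the targets of the design, the genes named by the study's question, and the 6 largest rises and falls per comparison among called coding genes with at least 1 TPM in the higher group. Per list it takes up to 4 called members with the smallest p plus called members that go against the rest. The part of the rule that asks for no overlap between libraries could not be applied. Some genes that the rule takes are not reported here. For noncoding features the 2 largest per direction were added. The calculations were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and tested on simulated data. For the comparison of aHepGHRkd with Control, over 14081 genes, 4.5% of 200 unrelated lists had a Fisher p under 0.05 and 100% of lists of 20 with 5 planted calls were found. Calls were placed at random gene by gene, so these figures check the code and not lists of genes that move together.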

Results

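Liver expression was summarised for 4 groups of 6 mice, all labelled male, 7 days after vector injection. The groups were GHR-intact mice (Control), mice with an adult-onset loss of the growth hormone (GH) receptor in hepatocytes (aHepGHRkd), and such mice with rat IGF1 (aHepGHRkd_rIGF1) or constitutively active STAT5b (aHepGHRkd_STAT5bCA) supplied to hepatocytes. STAT5b is the transcription factor that GH activates in liver, and IGF1 is the circulating growth factor made in response. All values are group values, folds and adjusted p from the authors' deposited table, which gives no value per animal. The depth per library is unknown, and the group values cannot be given an SD here. Of 20879 coding features, 10688 reached 1 TPM in Control, 10721 in aHepGHRkd, 10932 in aHepGHRkd_rIGF1 and 10745 in aHepGHRkd_STAT5bCA.

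The targeted gene and the supplied genes were examined first. Ghr (chromosome 15, 3267755 to 3533352 on mm9) stood at 180 TPM in Control, 55.1 in aHepGHRkd, 58.4 in aHepGHRkd_rIGF1 and 49.4 in aHepGHRkd_STAT5bCA in the authors' deposited table. Its ratio of aHepGHRkd over Control was 0.302 (adjusted p = 9.99e-61), and neither supplied gene changed it (ratios to aHepGHRkd of 0.989 and 0.924, adjusted p = 1 for both, in the authors' deposited table). The Ghr values cover the whole collapsed gene and non-hepatocyte cells, so they do not isolate the deleted part. Stat5b (chromosome 11, 100642045 to 100711895) was at 8.44, 10.6, 12.1 and 30.0 TPM in the same order, and rose 2.91-fold with STAT5bCA (adjusted p = 2.98e-39, the authors' deposited table), where reads of the mouse transgene are counted with those of the gene. Igf1 (chromosome 10, 87321010 to 87399792) was at 143, 26.2, 114 and 96.4 TPM. It fell to a ratio of 0.186 in aHepGHRkd in the authors' deposited table (adjusted p = 0.010). Its ratios of 3.89 with rIGF1 (adjusted p = 0.946) and 3.67 with STAT5bCA (adjusted p = 0.162) did not pass the test in the authors' deposited table. How many reads of the rat transgene align to mouse Igf1 is not known from a group value.

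**Figure D1:**
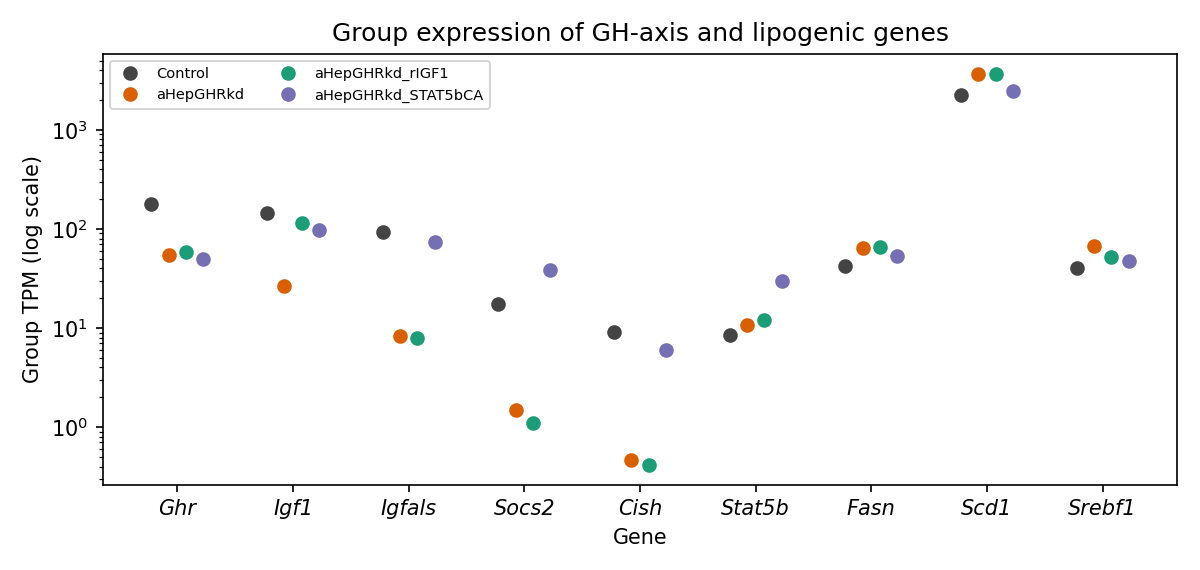
Group TPM (log axis) of 9 genes in the 4 groups, 1 point per group with no error bar because the table holds 1 value per group. Igfals, Socs2 and Cish are low in aHepGHRkd and aHepGHRkd_rIGF1 and higher in aHepGHRkd_STAT5bCA, and Srebf1 goes from 40.2 TPM in Control to 66.9 in aHepGHRkd.

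The comparison of aHepGHRkd with Control asked what loss of the receptor does to liver expression. Genes that respond directly to GH fell: Igfals, which encodes the acid-labile subunit that carries IGF1 in blood, to a ratio of 0.0899 (adjusted p = 7.02e-49), the feedback inhibitor Socs2 to 0.0833 (adjusted p = 5.72e-38) and Cish, another SOCS-family inhibitor, to 0.0505 (adjusted p = 3.64e-53), in the authors' deposited table. Of the 15 genes of the GH-IGF1 axis list, 7 fell and 1 rose (at least 7 and 3 adjusted over the list alone). The list was over-represented among lower genes (adjusted p = 8.25e-07, Fisher's exact test). The 7 include Ghr, which Cre itself targets. The riser was Stat5a (1.50-fold, adjusted p = 0.000241), and Prlr, the prolactin receptor, was among those that fell (ratio 0.452, adjusted p = 0.000376, the authors' deposited table). In total 493 features were called higher and 865 lower, of which 339 and 398 were coding. With a fold of at least 2, 216 rose and 526 fell, and 108 and 158 of these were coding.

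Genes with sex-biased expression in mouse liver were among the largest changes. All samples are labelled male, but the treatment protocol also names females, and animals of both sexes in a group would alter what these values mean. Xist is listed as the feature NC_INTER_CX_15394 and was matched by its RefSeq identifier. In the authors' deposited table, Xist, which is transcribed from the inactive X of females, lay between 0.0144 and 0.0414 TPM in the 4 groups. The Y-linked Ddx3y lay between 21.1 and 26.0 TPM there, and A1bg and Cyp2b13, which are specific to female liver, were at 0.154 and 0.0152 TPM in Control (genes chosen after the data were seen, the authors' deposited table). These values speak against females, most clearly in Control, since the treatments themselves move A1bg or Cyp2b13. However, the Xist feature overlaps 1 other feature, which may lower its count, and the table holds no female liver for comparison. The rankings that follow keep called coding genes with at least 1 TPM in the higher group. The 6 coding genes with the largest falls in the authors' deposited table were Hsd3b5 (ratio 0.00179, adjusted p = 3.98e-175, 96.0 TPM in Control and 0.169 in aHepGHRkd), Serpina1e (0.0120, from 9135 to 112 TPM), the organic anion transporter Slco1a1 (0.0215, adjusted p = 3.90e-196), Cyp4a12b (0.0271), Clec2h (0.0378) and Nipal1 (0.0393). The largest rises in the authors' deposited table were Cyp2b13 (0.0152 TPM in Control and 36.5 in aHepGHRkd), Cyp2b9 (209-fold, 1.35 to 287 TPM, adjusted p = 6.46e-88), Hao2 (31.3-fold), Slc22a29 (22.7-fold), Slc22a27 (20.9-fold) and Spink1 (20.2-fold). Of 27 male-biased genes 19 fell and 1 rose (at least 21 and 2 adjusted over the list alone, Fisher adjusted p = 2.44e-22 for lower), with a median log2 ratio of -2.12. Selenbp2 fell to 0.0421 (adjusted p = 1.36e-51), the complement gene C6 to 0.156 (adjusted p = 3.00e-124) and the major urinary protein Mup21 to 0.120 (adjusted p = 1.26e-133) in the authors' deposited table. The repressor Bcl6 rose 2.74-fold there (adjusted p = 3.35e-08, the authors' deposited table). Of 33 female-biased genes 14 rose and 6 fell (at least 16 and 7 adjusted over the list alone), and the list was over-represented in both directions (Fisher adjusted p = 2.64e-13 for higher and 0.00233 for lower). Those that fell in the authors' deposited table included Cyp2c40 (ratio 0.220), Cyp2c69 (0.175), the female-biased repressor Cux2 (0.281, adjusted p = 0.0399), Nipal1 and Cabyr (0.470). Some of these genes have close copies (Cyp2b9 and Cyp2b13, Cyp2c40 and Cyp2c69, and the relatives of Cyp4a12b, Serpina1e and Mup21). Reads shared between copies may affect their separate values. The 19 male-biased genes that fell include Mup1, Mup3, Mup7, Mup20, Mup21, Cyp4a12a, Cyp4a12b, Gstp1 and Gstp2. That count and its Fisher p may be affected as well.

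Genes of lipid and glucose metabolism named by the study's question changed by less than 3-fold. Gckr stood at a ratio of 1.19 (adjusted p = 0.375) in the authors' deposited table. In the glycolysis list, 2 of 16 genes rose and 1 fell (at least 2 and 1 adjusted over the list alone, Fisher adjusted p = 0.201 for higher). Khk, ketohexokinase, was higher (1.35-fold, adjusted p = 0.0211), and the faller was Pklr, liver pyruvate kinase (ratio 0.698, adjusted p = 0.0312, the authors' deposited table). For de novo lipogenesis and triglyceride synthesis 4 of 22 rose and 2 fell (at least 6 and 2 adjusted over the list alone, Fisher adjusted p = 0.0124 for higher). The risers in the authors' deposited table were the fatty acid synthase gene Fasn (1.50-fold, adjusted p = 0.0234), the desaturase Scd1 (1.60-fold, adjusted p = 0.0117), the transcription factor Srebf1 (1.63-fold, adjusted p = 0.010) and Gpam. The fallers in the authors' deposited table were Acacb (ratio 0.566, adjusted p = 5.81e-07) and Lpin1 (0.430, adjusted p = 9.59e-08). Acaca (1.32), Acly (1.01), Elovl6 (0.908), Mlxipl (0.882) and Thrsp (1.24) did not pass the test, with adjusted p of 0.603 for Acaca and 1 for the others in the authors' deposited table. In the lipid uptake and lipid droplet list 3 of 24 rose and 1 fell (at least 3 and 1 adjusted over the list alone, Fisher adjusted p = 0.0744 for higher). The fatty acid transporter Cd36 (2.90-fold, adjusted p = 9.58e-08), the droplet coat gene Plin2 (1.57-fold, adjusted p = 0.00136) and Vldlr (2.98-fold) rose, and hepatic lipase Lipc fell (0.655) in the authors' deposited table. Pparg was at 1.20 (adjusted p = 1, the authors' deposited table).

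Of 16 genes of gluconeogenesis and glycogen 3 fell and 1 rose (at least 5 and 1 adjusted over the list alone, Fisher adjusted p = 0.0417 for lower, 0.0662 with the background at 1 TPM). Pck1, which encodes the gluconeogenic enzyme PEPCK, fell to 0.506 (adjusted p = 3.93e-08), Got1 to 0.399 (adjusted p = 2.98e-10) and Tat to 0.683 (adjusted p = 0.0482) in the authors' deposited table. Gbe1 rose 1.48-fold (adjusted p = 0.00162), and G6pc was at 0.710 (adjusted p = 0.0886) in the authors' deposited table. The insulin signalling list had 0 of 20 higher and 1 lower (at least 1 lower adjusted over the list alone and at least 3 at an unadjusted p under 0.05). That gene was Grb14, an adaptor of the insulin receptor (ratio 0.744, adjusted p = 0.00241), while Insr (0.977), Irs1 (1.10), Irs2 (0.775) and Igfbp1 (1.06) had adjusted p = 1 in the authors' deposited table.

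Of 24 PPAR alpha targets and fatty acid oxidation genes 4 rose and 0 fell (at least 7 and 1 adjusted over the list alone, Fisher adjusted p = 0.0154 for higher). Ehhadh (1.56-fold, adjusted p = 0.00759) and Acaa1b (1.69-fold, adjusted p = 0.0067) of peroxisomal oxidation were among them in the authors' deposited table. Cholesterol synthesis had 3 of 20 higher and 0 lower (at least 9 and 0 adjusted over the list alone, Fisher adjusted p = 0.0417, 0.0662 with the background at 1 TPM). Sc5d (1.47-fold) and Msmo1 (1.57-fold) were among them in the authors' deposited table. In bile acid synthesis and transport 2 of 19 rose, Akr1d1 (1.48-fold) and Slco1a4 (2.08-fold), and the bile acid uptake carrier Slc10a1 fell to 0.496 (adjusted p = 7.19e-18), in the authors' deposited table. These counts were at least 4 and 2 adjusted over the list alone (Fisher adjusted p = 0.258 for higher). Of 14 pericentral genes 3 rose and 0 fell (at least 4 and 0 adjusted over the list alone, Fisher adjusted p = 0.0240). Of 13 periportal genes 3 fell and 0 rose (at least 5 and 0 adjusted over the list alone, Fisher adjusted p = 0.0272). The pericentral risers were Lgr5 (1.61-fold), Lect2 (2.31-fold) and Cyp2c37 (1.88-fold), and the periportal fallers were the urea cycle gene Asl (0.643), Cyp2f2 (0.533) and Etnppl (0.324), in the authors' deposited table. Among 19 xenobiotic receptor targets 8 rose and 1 fell (at least 10 and 1 adjusted over the list alone, Fisher adjusted p = 9.04e-08). Cyp2b10 (7.68-fold, adjusted p = 6.28e-18) and Gsta2 (2.20-fold, adjusted p = 9.83e-13) were among the risers and Cyp3a13 was lower (0.691) in the authors' deposited table. Of 18 hepatocyte identity genes, Ttr rose 1.38-fold and Trf, transferrin, fell to 0.598 (adjusted p = 1.43e-08) in the authors' deposited table (at least 1 higher and 2 lower adjusted over the list alone, Fisher adjusted p = 0.811 for both directions).

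Of 21 acute phase genes 10 were higher, 2 lower and 9 not called (at least 11 and 2 adjusted over the list alone, Fisher adjusted p = 3.09e-10 for higher). In the authors' deposited table the iron-binding lipocalin Lcn2 rose 4.36-fold (adjusted p = 1.48e-10), Orm2 3.96-fold (adjusted p = 5.90e-13), Steap4 2.67-fold (adjusted p = 2.04e-06) and Il1rn 2.57-fold (adjusted p = 4.35e-08). Crp fell to 0.387 (adjusted p = 5.06e-22) and Lbp to 0.678 (adjusted p = 0.0382) in the authors' deposited table. In the cell cycle list 5 of 24 rose and 1 fell (at least 9 and 1 adjusted over the list alone, Fisher adjusted p = 0.00179 for higher). The cyclin D gene Ccnd1 (3.66-fold, adjusted p = 3.13e-18), the cyclin-dependent kinase inhibitor Cdkn1a (4.03-fold, adjusted p = 9.37e-24), Mcm2 (1.96-fold) and Mcm4 (1.65-fold) were among the risers and Rrm2 fell (0.629) in the authors' deposited table. Mki67 was at 1.54 (adjusted p = 0.206, the authors' deposited table). The circadian list had 1 of 19 lower (Per1, 0.657) and 0 higher, ER stress and heat shock 1 of 15 higher (Dnajb9, 1.43-fold) and 0 lower, and the immediate early genes 1 of 12 higher (Btg2, 1.87-fold) and 0 lower, in the authors' deposited table. Adjusted over the list alone these were at least 1 lower, 2 higher, and 1 higher with 1 lower, and the smallest Fisher adjusted p of the 3 lists was 0.701.

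Markers of other cell types gave few calls. None of 16 stellate cell and fibroblast, 15 Kupffer cell, 15 sinusoidal endothelial, 10 cholangiocyte, 16 lymphocyte, 10 neutrophil or 23 interferon response genes was called in the authors' deposited table. Adjusted over the list alone the count was also at least 0 in each, and at an unadjusted p under 0.05 it was at least 1 cholangiocyte, 2 lymphocyte and 2 interferon genes. The median log2 ratio was 0.25 for Kupffer cells, above 99.9% of random lists matched on TPM, and 0.33 for lymphocytes, above 96.9%. It was 0.12 for stellate cells (86.1%), 0.04 for endothelial cells (57.9%), -0.06 for cholangiocytes (18.3%), -0.01 for neutrophils (36.6%) and 0.06 for the interferon genes (75.5%). These percentages describe the lists and are no test, since genes of 1 cell type may move together between animals. Of 9 erythrocyte genes Alas2 was lower (ratio 0.595, adjusted p = 4.52e-09, the authors' deposited table), and at least 6 were lower adjusted over the list alone, with a median log2 ratio of -0.77 (above 0% of random lists). Of 13 adipose and pancreas genes, 7 of which were listed at 0 in both groups, Cfd (0.156) and Cela2a (0.579) were lower in the authors' deposited table (at least 2 adjusted over the list alone, Fisher adjusted p = 0.0362).

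The comparison of aHepGHRkd_rIGF1 with aHepGHRkd asked what restoring IGF1 changes. It gave 3 features higher and 3 lower in the authors' deposited table, against at least 740 of 48257 detected features at an unadjusted p under 0.05. These 740 are all the values under 1. A feature with a value of exactly 1 may also have an unadjusted p under 0.05 and is not counted. The 740 are a lower limit, so setting them against the 0.05 that no effect would give cannot tell whether more changed. The 2 coding genes were Wfdc21 (548 to 193 TPM, ratio 0.329, adjusted p = 0.0114) and the acute phase gene Orm1 (2091 to 873 TPM, ratio 0.388, adjusted p = 0.0499), both lower, in the authors' deposited table. Wfdc21 had also been lower in aHepGHRkd than in Control (ratio 0.394, adjusted p = 0.00169), and Orm1 had not been called (0.895, adjusted p = 1, the authors' deposited table). The 4 noncoding features were NC_INTRA_C2_33673 (3.67-fold higher, overlapping Rapgef4), NC_INTRA_C3_36552 (1.88-fold higher), GM42901 (6.70-fold higher, 0.0490 to 0.355 TPM) and NC_AS_C11_20912 (ratio 0.355), which overlaps Wfdc21, in the authors' deposited table. The first of these was the only feature called in the knockdown that rIGF1 moved back toward Control, and it stood at 11.7, 1.10, 4.42 and 6.17 TPM in Control, aHepGHRkd, aHepGHRkd_rIGF1 and aHepGHRkd_STAT5bCA, in the authors' deposited table.

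Target genes of GH stayed near the knockdown level with rIGF1 in the authors' deposited table, with ratios to aHepGHRkd of 0.875 for Igfals, 0.690 for Socs2 and 0.833 for Cish (adjusted p = 1 for each). Fasn (0.962), Scd1 (0.917) and Pck1 (1.04) had adjusted p = 1, and Srebf1 was at 0.728 (adjusted p = 0.961), in the authors' deposited table. Only the acute phase list had a called member, Orm1, and none of the other 28 lists had one. Adjusted over the list alone, at least 10 of 21 acute phase genes were lower (median log2 ratio -0.53), at least 7 of 9 erythrocyte genes higher (median 1.00), at least 5 of 16 stellate cell and fibroblast genes higher (median 0.58), at least 3 of 23 interferon genes lower (median -0.19) and at least 2 of 15 ER stress genes lower (median -0.23), and the remaining lists had at least 0. Among those remaining lists, at an unadjusted p under 0.05, at least 3 cholesterol synthesis, 2 lipogenesis and 2 female-biased genes were lower. At least 2 GH-IGF1 axis genes were higher. The median log2 ratios of these 4 lists were -0.23 (above 0% of random lists), -0.04 (81.0%), -0.16 (0%) and 0.09 (99.7%). Of the remaining cell type lists, cholangiocytes had a median log2 ratio of 0.36 (above 99.9% of random lists), adipose and pancreas genes 0.85 (99.9%), neutrophils -0.33 (0.29%), endothelial cells 0.08 (89.4%), Kupffer cells -0.01 (40.2%) and lymphocytes -0.02 (15.2%). These list-alone and unadjusted counts rest on the p column being Benjamini-Hochberg adjusted over the features detected in either group. The blood and fibroblast markers moved in the same comparison as the acute phase genes. The median log2 ratio of the erythrocyte list was -0.77 in aHepGHRkd over Control, 1.00 with rIGF1 and 0.92 with STAT5bCA over aHepGHRkd. That of the acute phase list was 0.55, -0.53 and -0.23, and that of the stellate list 0.12, 0.58 and -0.04. The aHepGHRkd libraries enter all 3 comparisons. For the erythrocyte and acute phase lists, a shift in that group alone therefore cannot be told apart from effects of knockdown and vectors.

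The comparison of aHepGHRkd_STAT5bCA with aHepGHRkd asked what active STAT5b changes when the receptor is missing. It gave 780 features higher and 136 lower in the authors' deposited table, of which 370 and 85 were coding. With a fold of at least 2 the counts were 574 and 48. The rankings that follow keep called coding genes with at least 1 TPM in the higher group. Among the 6 largest coding rises in the authors' deposited table were the sulfotransferase Sult3a2 (listed at 0 in the other 3 groups, 43.5 TPM here), A1bg (0.228 to 600 TPM), Hsd3b1 (0.00803 to 27.2 TPM), Cyp2c69 (0.583 to 490 TPM) and 2010106E10Rik (listed at 0 in aHepGHRkd, 6.62 TPM here). A1bg lies on chromosome 15 from 60749144 to 60752825 on mm9, and in Control it stood at 0.154 TPM in the authors' deposited table. The largest falls in the authors' deposited table were Chil1 (ratio 0.220), Gm10639 (0.274), the keratin Krt23 (0.293), H2-Q1 (0.374), Cyp2b10 (0.389) and Cyp2c55 (0.397), and the first 5 of these had been called higher in aHepGHRkd.

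Direct targets rose again: Igfals 9.06-fold (adjusted p = 3.23e-44), Socs2 26.7-fold (adjusted p = 1.64e-89), Cish 13.2-fold (adjusted p = 1.56e-33) and Prlr 16.9-fold (adjusted p = 1.21e-75) in the authors' deposited table. Socs2 (38.3 against 17.6 TPM) and Prlr (68.5 against 9.26 TPM) then lay above Control, and Igfals (73.8 against 93.0 TPM) and Cish (5.95 against 9.21 TPM) below it, by the group values of the authors' deposited table. Of the 15 GH-IGF1 axis genes 6 rose and 1 fell, Igfbp2 (ratio 0.575, adjusted p = 0.00132, the authors' deposited table), with at least 7 and 2 adjusted over the list alone and a Fisher adjusted p = 1.43e-05 for higher. The 6 include Stat5b, whose reads include those of the supplied transgene. Of 33 female-biased genes 18 rose and 0 fell (at least 20 and 1 adjusted over the list alone, Fisher adjusted p = 8.58e-19). They included Cux2 (102-fold, adjusted p = 3.33e-167), Cyp2c40 (30.0-fold) and Sult3a1 (0.228 to 168 TPM) in the authors' deposited table. Of 27 male-biased genes 10 rose and 5 fell (at least 11 and 6 adjusted over the list alone), and both directions were over-represented (Fisher adjusted p = 1.85e-08 and 7.07e-06). Hsd3b5 rose from 0.169 to 30.7 TPM, Slco1a1 14.7-fold and Cyp4a12b 13.6-fold in the authors' deposited table. Cyp2d9 (0.523), Cyp2u1 (0.501), Elovl3 (0.479), Mup20 (0.644) and Bcl6 (0.610) fell, in the authors' deposited table.

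In de novo lipogenesis and triglyceride synthesis 1 of 22 rose, Acacb (2.40-fold, adjusted p = 5.20e-21), and 0 fell, in the authors' deposited table (at least 1 and 0 adjusted over the list alone, Fisher adjusted p = 1). Scd1 (ratio 0.697, adjusted p = 0.198), Srebf1 (0.738, adjusted p = 0.440), Fasn (0.874, adjusted p = 1), Cd36 (0.920, adjusted p = 1) and Pck1 (1.30, adjusted p = 0.776) did not pass the test in the authors' deposited table. No gene of the glycolysis, gluconeogenesis, insulin signalling or cholesterol synthesis lists was called, and adjusted over the list alone at least 0, 1, 1 and 2 rose. At an unadjusted p under 0.05 at least 3, 5, 1 and 5 of their genes were counted. Lipid uptake and lipid droplets had 1 of 24 higher (Abhd5, 1.43-fold) and 1 lower (Vldlr, 0.577) in the authors' deposited table, and at least 3 and 3 adjusted over the list alone. PPAR alpha targets had 4 of 24 higher and 1 lower (at least 4 and 1 adjusted over the list alone, Fisher adjusted p = 0.0231 for higher). The fatty acid hydroxylases Cyp4a10 (2.78-fold), Cyp4a14 (2.83-fold) and Cyp4a31 (1.99-fold) and the thioesterase Acot1 (3.50-fold) rose in the authors' deposited table.

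Xenobiotic receptor targets had 6 of 19 lower and 0 higher (at least 9 and 1 adjusted over the list alone, Fisher adjusted p = 1.85e-08). Cyp3a11 (0.625) and Cyp2c29 (0.555) were among them in the authors' deposited table. Of 21 acute phase genes 3 fell, Orm2 (0.479), Steap4 (0.496) and Hamp (0.603), and 3 rose, Crp (2.17-fold), Apcs (2.51-fold) and Cp (1.78-fold), in the authors' deposited table. These counts were at least 8 and 4 adjusted over the list alone (Fisher adjusted p = 0.00222 for lower and 0.106 for higher). In the cell cycle list 5 of 24 rose and 0 fell (at least 9 and 1 adjusted over the list alone, Fisher adjusted p = 0.00222, 0.375 with the background at 1 TPM). They were low in level in the authors' deposited table, such as Mki67 (0.297 to 0.774 TPM, 2.67-fold), Ccnb1 (0.0958 to 0.730 TPM) and Cdk1 (0.206 to 0.584 TPM). Single members moved elsewhere. In the authors' deposited table, Slc10a1 rose 1.46-fold among 19 bile acid genes, Slc1a2 rose 1.58-fold and Lgr5 fell (0.480) among 14 pericentral genes, and Trf rose 2.03-fold and Foxa2 1.47-fold among 18 hepatocyte identity genes. Hspa1b fell (0.539) among 15 ER stress and heat shock genes, and Alas2 fell (0.666) among 9 erythrocyte genes in the authors' deposited table. At least 6 erythrocyte genes were higher and 1 lower adjusted over the list alone, with a median log2 ratio of 0.92. Adjusted over the list alone the bile acid list had at least 1 higher, the pericentral list 2 higher and 3 lower, the identity list 2 higher and the ER stress list 1 lower. The periportal, circadian, immediate early, interferon, stellate, Kupffer, endothelial, cholangiocyte, lymphocyte, neutrophil, and adipose and pancreas lists had 0 called, also at least 0 adjusted over the list alone. At an unadjusted p under 0.05 at least 1 periportal, 2 immediate early, 1 interferon, 1 lymphocyte and 1 adipose or pancreas gene were counted. Among these cell type and interferon lists the median log2 ratio was 0.11 for Kupffer cells (above 98.8% of random lists), 0.08 for interferon genes (98.3%), 0.34 for adipose and pancreas genes (96.3%), 0.14 for neutrophils (84.3%), -0.04 for stellate cells (31.9%) and for endothelial cells (27.6%), -0.28 for lymphocytes (1.46%) and -0.22 for cholangiocytes (1.29%).

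**Figure D2:**
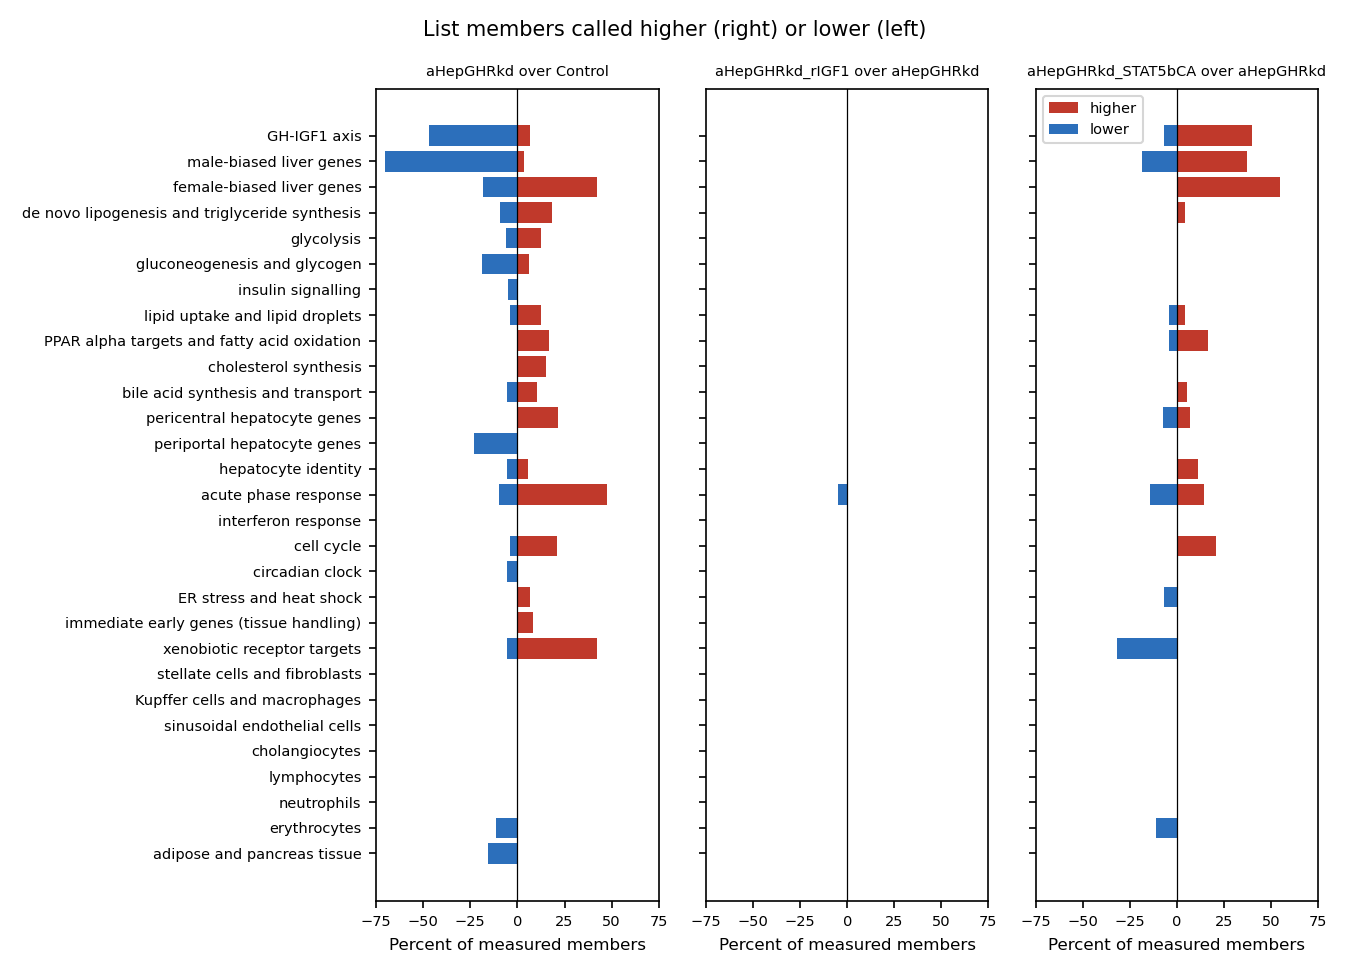
Percent of the measured members of each of the 29 gene lists called higher (bars to the right) or lower (bars to the left) in the 3 comparisons of the authors' deposited table. Male-biased genes lie mostly to the left for aHepGHRkd over Control (19 of 27) and female-biased genes to the right for aHepGHRkd_STAT5bCA over aHepGHRkd (18 of 33), and the middle panel holds 1 short bar.

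Genes called in the knockdown were followed into the other groups. STAT5bCA moved 136 of the 398 lower coding genes up and 41 of the 339 higher ones down, and it moved 4 and 8 further in the knockdown's direction, in the authors' deposited table. Among genes moved back were Igfals, Socs2, Cish, Hsd3b5, Serpina1e, Acacb and Trf from the lower set and Cyp2b10, Cyp2a5, Orm2, Bcl6 and Krt23 from the higher set. Elovl3 and Mup20 were among the 4 called lower in both comparisons. Independent lists of these sizes would share 8.66 and 1.70 genes in those 2 opposite directions. In 100 simulated draws with the called knockdown effects, no effect of the vector and a shared aHepGHRkd group, 0.01 genes on average were moved back. With no effect anywhere it was 0, but there only 0.06 genes on average were called in the knockdown. A vector without effect leaves almost nothing to call, and errors were drawn gene by gene. These draws therefore set no bound on calls that the shared group could add among the 370 higher and 85 lower coding genes with STAT5bCA. The aHepGHRkd libraries enter both comparisons and could not be split, so part of the excess may come from them. Over all features 350 were moved back, and over noncoding ones 173. A further 226 coding genes were called higher and 40 lower with STAT5bCA without a call in the knockdown. With rIGF1, 0 of the 339 and 0 of the 398 coding genes and 1 noncoding feature were moved back.

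**Figure D3:**
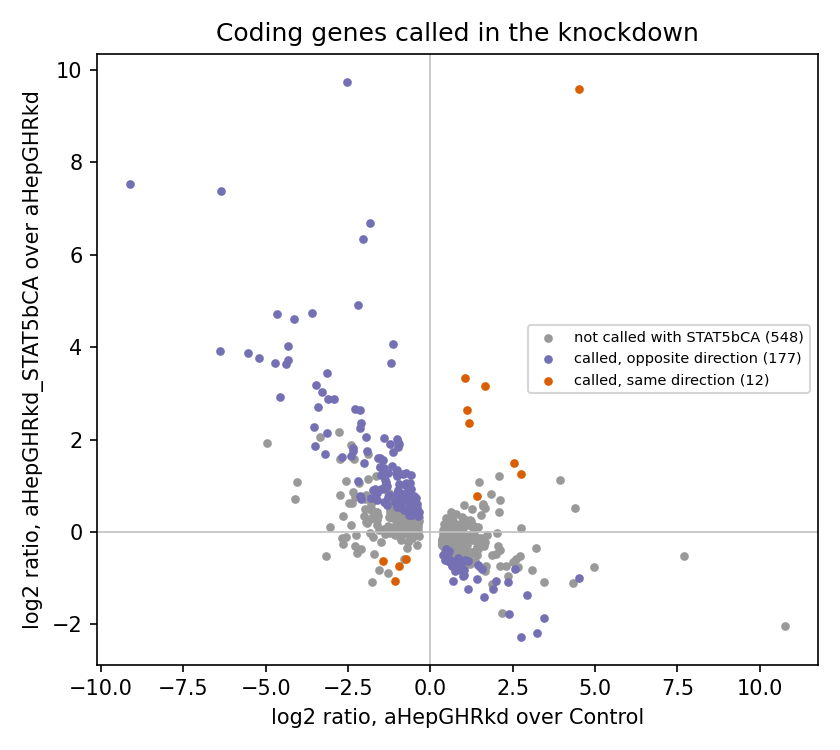
Log2 ratio of aHepGHRkd over Control (x axis) against that of aHepGHRkd_STAT5bCA over aHepGHRkd (y axis), 1 point per coding gene called in the knockdown. Points called in the opposite direction with STAT5bCA (177) lie mostly in the upper left, where 136 genes lower in the knockdown rose.

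No test of rIGF1 or STAT5bCA livers against Control, or against each other, was available from the deposited values, and these comparisons are given as group TPM on the log2(TPM + 1) scale only. Of the 398 coding genes lower in the knockdown, 94 lay at least 2-fold below Control in aHepGHRkd, 100 in aHepGHRkd_rIGF1 and 51 in aHepGHRkd_STAT5bCA. The 339 higher genes had 64, 57 and 48 at least 2-fold above Control. Of the 27 male-biased genes 18, 15 and 16 lay at least 2-fold below Control in these groups, and of the 33 female-biased genes 11, 9 and 22 lay at least 2-fold above it. Over all coding features, 71 lay at least 2-fold above and 114 below Control in aHepGHRkd_rIGF1, and 104 above and 58 below in aHepGHRkd_STAT5bCA. Between aHepGHRkd_STAT5bCA and aHepGHRkd_rIGF1, 115 were at least 2-fold higher and 21 lower. These counts of group values carry no test, and they depend on the pseudocount. With 0.1 in place of 1, the 398 lower genes had 145, 140 and 71 below Control and the 339 higher ones 100, 92 and 71 above it, in the group order above. The male-biased counts became 19, 16 and 18 and the female-biased ones 15, 16 and 25, so that aHepGHRkd and aHepGHRkd_rIGF1 changed order for the lower genes and the female-biased list.

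Noncoding features made up much of the calls, with 154 higher and 467 lower in aHepGHRkd than in Control and 410 higher and 51 lower with STAT5bCA, in the authors' deposited table. The rankings that follow keep called features with at least 1 TPM in the higher group. The largest falls in the knockdown were NC_INTER_C12_22922 (14.6 to 0.0310 TPM) and NC_INTER_C12_10880 (75.2 to 0.339 TPM) in the authors' deposited table, at 105319512 to 105321314 and 105316130 to 105318954 of chromosome 12. The largest rises were NC_INTER_C12_10621 (5.35-fold) and NC_AS_C4_37406 (5.06-fold), in the authors' deposited table. With STAT5bCA the largest rises were NC_INTER_C10_18314 (listed at 0 in aHepGHRkd, 33.2 TPM with STAT5bCA), which lies 57 bp from Sult3a2 on chromosome 10, and NC_INTER_C10_18328 (listed at 0, then 2.05 TPM), in the authors' deposited table. The largest falls were NC_AS_C19_14998 (0.373) and NC_AS_C3_2894 (0.403), which overlaps Cyp2u1, in the authors' deposited table. Since the use of strand in counting is not given, reads of such features cannot be told from those of the coding genes they overlap.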

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

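The alternatives with a 1 TPM floor, coding features only and the higher background were chosen after the data were seen. With a fold of at least 2, the 493 higher and 865 lower features of aHepGHRkd over Control became 216 and 526, the 136 lower ones with STAT5bCA became 48, and the 350 moved back by STAT5bCA became 198. With coding features only, 398 were lower in aHepGHRkd, 370 higher and 85 lower with STAT5bCA, 0 higher with rIGF1, 0 moved back by rIGF1 and 177 moved back by STAT5bCA. With at least 1 TPM in the higher group, 464 rather than 780 features were higher with STAT5bCA. These settings keep subsets of the same features, which lowers a count by construction. With a pseudocount of 0.1 in place of 1, the counts of coding genes at least 2-fold above and below Control by group TPM went from 71 and 114 to 237 and 205 for aHepGHRkd_rIGF1 and from 104 and 58 to 285 and 136 for aHepGHRkd_STAT5bCA, and those of aHepGHRkd_STAT5bCA against aHepGHRkd_rIGF1 from 115 and 21 to 284 and 164. For the sets of genes called in the knockdown it moved 94 to 145 below Control and 64 to 100 above it in aHepGHRkd, and 57 to 92 above it in aHepGHRkd_rIGF1. For aHepGHRkd_rIGF1, female-biased genes above Control went from 9 to 16 and male-biased ones above it from 1 to 2, and for aHepGHRkd female-biased genes below Control went from 3 to 6. A smaller pseudocount lets genes near 0 TPM pass. With the background of at least 1 TPM, the over-representation of the gluconeogenesis list among lower genes and of the cholesterol synthesis list among higher genes in the knockdown no longer passed (adjusted p = 0.0662 for both), nor did that of the cell cycle list with STAT5bCA (adjusted p = 0.375); the cause was not tested. Of the 178 alternative values 152 stayed on the same side of the threshold or within 1.5 times, 23 moved further and 3 weakened. A reversal was not among the outcomes that could be recorded. Many values were list p-values far from the threshold, so the 152 is no measure of robustness. No paired analysis was possible because the table holds no value per animal. For the same reason the alternatives set before the data were examined that need libraries, namely normalization, low-count filter, DESeq2, limma-voom, 2-group fits, the animal number as covariate, left-out libraries, camera with an estimated correlation and fry were not run, and other splits of the animals could not be drawn. Depth is unknown.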

Other observations

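The test of p53 target genes was planned before its values were seen, and the tests on noncoding features and on Igf1 were chosen after the results they concern were seen. Of 26 p53 target genes whose values had not been looked at, 8 were called higher in aHepGHRkd than in Control and 1 lower in the authors' deposited table. The risers were Ccng1 (1.92-fold, adjusted p = 1.35e-10), the stress cytokine gene Gdf15 (2.51-fold, adjusted p = 1.04e-07), Eda2r (2.64-fold, adjusted p = 3.29e-05), Trp53inp1 (1.46-fold), Aen (1.47-fold), Zmat3 (1.41-fold), Dcxr (1.33-fold) and Rps27l (1.34-fold), in the authors' deposited table. Trp53inp2 was the one called lower. Cdkn1a (11.8 to 47.9 TPM), Phlda3 (4.25-fold, adjusted p = 4.19e-19), Psrc1 (5.68-fold) and Btg2, which led to the list, were higher as well in the authors' deposited table.

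The 26 genes were over-represented among higher coding genes (one-sided Fisher's exact p = 1.11e-07), as a rise of p53 targets in the Cre-treated knockdown needs. If loss of STAT5b activity alone raised them, STAT5bCA was predicted to move the raised members back toward Control, which it did not. The 12 raised members had a median log2 ratio of 0.92 in the knockdown and of -0.0034 with STAT5bCA over aHepGHRkd (quartiles -0.06 and 0.14). Of them 0 were called lower with STAT5bCA, and the bound set for a return toward Control was -0.46. STAT5bCA instead raised 4 of the 26 targets (Eda2r, Plk2, Ckap2 and Tnfrsf10b, Fisher's exact p = 0.00431), of which Eda2r was among the 12 (1.73-fold, adjusted p = 0.0233, the authors' deposited table). The 339 higher coding genes as a set had medians of 0.72 in the knockdown and -0.24 with STAT5bCA, also short of a return of that proportion. Their quartiles with STAT5bCA were -0.48 and -0.05, so the median of the 12 lay above the upper one. STAT5bCA is constitutively active and returned that set only in part, so the missing return does not exclude loss of STAT5b activity. The median of the 12 with rIGF1 was -0.04. Cre recombinase itself may raise such genes, but 0 groups received Cre without the knockdown, so Cre and loss of Ghr cannot be told apart here. Of paths other than STAT5b, loss of IGF1 was addressed by the rIGF1 group. There 0 of the 26 targets and 0 of the 4 that led to the list were called lower, in a comparison with 6 calls in all. Other effects of Ghr loss remain untested.

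Noncoding features often changed with the coding gene they overlap. Over 451 pairs on mm9 whose coding gene was called in the knockdown, the median absolute difference in log2 ratio was 0.35, against 1.15 for random called genes. The noncoding feature was called in the same direction in 166 pairs and in the other in 3. Both shared reads and separate transcription that follows the neighbour may give this median of 0.35. In 348 antisense pairs it was 0.30, against 1.14 at random, and in 103 same-strand pairs 0.54, against 1.26, which shared reads allow. The share of pairs with adjusted p within 10% of each other was 3.45% for antisense and 0% for same-strand pairs (0.598% and 0.437% at random). It decides nothing, since it is low even for same-strand pairs, which may share reads. Which explanation applies stays open without strand or reads, and the noncoding counts may therefore repeat coding changes.

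Igf1 had a weak p for its fold. Its peers were coding genes of 20 to 500 TPM with a log2 ratio within 0.5 of that of Igf1. There were 9 in the knockdown and 18 with STAT5bCA, and a gene may be counted in both. None of these peers had an adjusted p as high (0%). The highest among them was 0.00244 against 0.010 in the knockdown and 0.000314 against 0.162 with STAT5bCA, in the authors' deposited table. Counting noise at that level is thus argued against. A Control animal among those labelled aHepGHRkd is excluded by the ratio of 0.00179 for Hsd3b5, far below the bound of 0.1, and a STAT5bCA animal by the A1bg TPM ratio of 0.000379 of aHepGHRkd over aHepGHRkd_STAT5bCA. Rat IGF1 reads in 1 or more aHepGHRkd animals, or an rIGF1-treated animal among them, may also widen the spread of Igf1, and this cannot be told apart from spread between animals because 6 features were called between those 2 groups and no value per animal was used.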
